A study of Drosophila melanogaster with 2 samples.

How the data were processed

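The series comprised 2 biological replicates (numbers 2 and 3 in the labels) of an anti-GFP ChIP-seq experiment on Drosophila melanogaster embryos, 0 to 24 hours old and of mixed sex, from a line stably expressing maf-S with a C-terminal eGFP tag. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. A control experiment is named in the labels; control data were not analysed here. The 2 replicates came from separate biosamples per the labels.

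The deposited files used here were peak lists on the dm6 and dm3 assemblies, per the labels: for each assembly a list for each replicate and a list from the pooled replicates, described per the labels as peaks and background for the irreproducible discovery rate (IDR) step, and the list that passed the authors' optimal IDR threshold. Each row gave an interval, a summit, a signal value per peak assigned by the authors' peak caller, and a q-value on the −log10 scale, as deposited by the authors. The aligner, the peak caller, the IDR threshold, the read depth and any read filtering were not given in the sources used here. The replicate and pooled lists each ended at 30000 rows, so a low rank in them need not be a binding site. On dm6 the thresholded list was exactly the 3205 peaks of highest signal of the pooled list, all with the same −log10 q-value of 3.81, so this value was not used for ranking. In 84.96% of thresholded peaks the interval was 390 bp wide, a width set by the caller, so widths were not compared between sites. A single interval was listed with 2 summits, and both rows were kept. The signal was used to describe, rank and filter peaks within a list and to correlate matched peaks between replicates; its scale was not assumed equal between lists.

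Coordinates are 1-based on dm6. Sequence was read from the RefSeq copy of Drosophila Release 6, the assembly of dm6, and genes from Ensembl release 115; the chromosome lengths held every dm6 peak. Genes of transposable elements were left out, which left 18277 genes, 13968 of them protein-coding, and 24111 start sites. No dm3 sequence or annotation was used, so the dm3 lists entered only counts, widths, signal values and the overlap and correlation of their replicates. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

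All tests, lists and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made later. Replicate overlap counted intervals sharing at least 1 bp among the N strongest peaks of each replicate, N being the number of thresholded peaks, with 100 random placements on the same arm as chance level. Thresholded peaks were matched to replicate peaks by summits within 150 bp; correlations across matched peaks used log2 signal and 100000 permutations. Summits were assigned by priority to promoter (within 500 bp of any start site), 5' UTR, 3' UTR, coding exon, other exon, intron or intergenic sequence, and compared with 1000 random placements on the same arm. Sequence motifs were searched on both strands within 100 bp of each summit and in windows of the same width 1 kb up- and downstream that touched no thresholded peak, with two-sided Fisher's exact tests, odds ratios with 95% intervals, and Benjamini-Hochberg adjustment over the 18 sequences of the panel. The same windows were searched for all words of 6 to 8 bp. Shares have exact (Clopper-Pearson) binomial 95% intervals, and a count of 0 was taken to allow up to 3 counts.

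For gene lists, a gene was counted as bound when a thresholded summit lay within 1 kb of any of its start sites, and the share was compared with that of all other protein-coding genes (for RNA genes, all other genes) by Fisher's exact test, adjusted over 19 lists. The lists held antioxidant and Cnc-Keap1 response genes, glutathione S-transferases, cytochrome P450 genes, UDP-glycosyltransferases, proteasome subunits, autophagy genes, cytosolic ribosomal proteins, heat shock proteins, basic leucine zipper factors, Hox and segmentation factors, ecdysteroid synthesis genes, markers of somatic muscle, of neurons and glia, of trachea and epidermis, of midgut, fat body and haemocytes, and of the germ line, replication-dependent histones, transfer RNA genes, and small nucleolar and small nuclear RNA genes. Of 1258 requested members 1250 were matched to the annotation. Neighbouring genes can share a peak, so genes of a list are not fully independent. The genes named are those nearest to the 15 strongest peaks, maf-S, cnc, Keap1, Jra, kay, tj, Gclc, Gclm, GstD1, ref(2)P and Trxr1 in any case, up to 3 bound members of each list with the highest signal, and those nearest to the 5 strongest peaks with the Cnc-Maf sequence; others, named where counts were small, were chosen after their values were seen. Chosen after the data were examined were the position of summits relative to start sites, the GC-matched flanks of the panel and the word search, the motif tests at the peaks of gene lists, and those of the Cnc-Maf sequence at promoters without a peak and at peaks away from promoters.

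The procedures were tested on simulated data. With no planted word, 0 words were called at 6, 7 or 8 bp in 3000 windows; with the Cnc-Maf site planted in 150 windows, the motif odds ratio was 9.17 and 10 words of 8 bp were called, 4 of them inside the planted site. Random placements of the 3205 peaks called 0.2 gene lists per placement on average. Alternatives covered the threshold, each replicate alone (the N strongest peaks of the other), matching and promoter distances, windows, control windows, motif definitions, gene assignment, the background genes (including 10000 random lists matched for gene length), and the dm3 lists.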

Results

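Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the binding sites of maf-S, the small Maf basic leucine zipper protein of Drosophila melanogaster, in whole embryos of mixed sex collected 0 to 24 hours after laying. The flies carried a transgene that expresses maf-S fused at its C-terminus to green fluorescent protein (eGFP), and the protein was precipitated with an antibody against GFP. Small Maf proteins lack a transactivation domain and bind DNA as dimers, in flies with the Cap'n'collar (cnc) factor of the antioxidant response. The series held 1 group of 2 biological replicates, numbered 2 and 3, and no other condition, so the design implies a description of the bound sites and a comparison of the replicates. The sequencing depth of the libraries was not given in the sources used here; each replicate contributed a list of 30000 ranked peaks, and the intervals below cover counting error over peaks only. The thresholded list of the authors held 3205 peaks on the dm6 assembly, with signal values from 72.3 to 1703 and a median of 109.

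The gene of the tagged protein itself lay under a weak peak. The peak at 2R:20641450-20641839 (dm6) had its summit at 20641645, inside the 3' end of maf-S (2R:20640976-20641668, plus strand), 669 bp from the start site of maf-S and 97 bp from that of the neighbouring gene CG11110. Its signal was 79.8, rank 2730 of the thresholded list, and the matching peak ranked 1415 in replicate 2 and 7626 in replicate 3. The window around this summit held a match to the Cnc-Maf sequence, TGCCCAGTCAC. The summits of those replicate peaks lay just outside the gene. Within 20 kb of maf-S the thresholded list had 1 further peak, at the promoter of FAM21 (2R:20623393-20623563, signal 288, rank 220), and each replicate had 14 peaks before thresholding. The partner gene cnc carried a peak at 3R:23189904-23190293 (signal 132, rank 1142), within its span and 320 bp from a start site, and Keap1, whose product holds Cnc in check, had a summit 800 bp from its start site (3R:17080675-17080804, signal 219, rank 426).

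maf-S-eGFP was found mainly at promoters and hardly ever in coding sequence. Of the 3205 summits, 1889 (58.9%, exact binomial 95% interval 57.2 to 60.6) lay within 500 bp of an annotated transcription start site, against 13.6% when the peaks were placed at random on the same arms, a ratio of 4.33. The one-sided permutation p was 0.001, the smallest that 1000 placements can give. At protein-coding start sites the summits sat upstream: 1501 of 1808 (83.0%) were on the 5' side, with a median position 81 bp before the start. Introns held 947 summits (29.5% against 39.4% at random) and intergenic sequence 307 (9.58% against 27.2%). Only 4 summits (0.125% against 13.1%) fell in coding exons away from start sites. Chosen after their values were seen, these 4 had Cib2, CycY, lncRNA:CR46002 and asRNA:CR46005 as the genes with the nearest start sites, and the strongest was near Cib2 (signal 589, rank 47). The 3' untranslated regions held 23 summits (0.718% against 5.06%). Introns, intergenic sequence, coding exons and 3' untranslated regions each held fewer summits than any random placement (permutation p = 0.001 each, one-sided, again the smallest possible). The classes share a fixed total, so the promoter excess by itself lowers the other classes. The lower intron share therefore does not show that introns were avoided, and introns held 947 of the 1316 summits outside promoters. The 5' untranslated regions held 15 summits (0.468% against 0.786%, permutation p = 0.0270) and other exons 20 (0.624% against 0.812%, permutation p = 0.147).

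**Figure D1:**
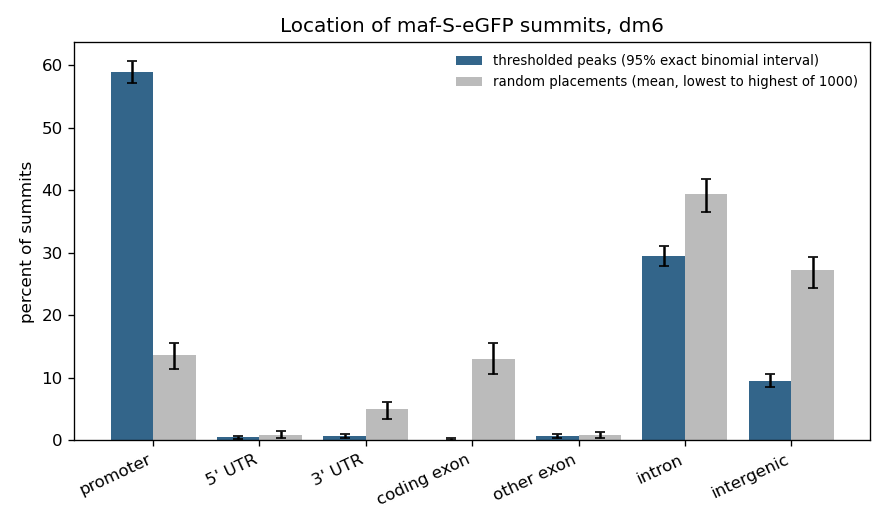
Percent of the 3205 thresholded maf-S-eGFP summits in each class of annotation (blue, with exact binomial 95% intervals) beside the mean of 1000 random placements on the same arms (grey, bars from the lowest to the highest placement). Promoters hold 58.9% of summits against 13.6% at random, and coding exons 0.125% against 13.1%.

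The chromosome arms shared the peaks roughly by their length. Chromosome 4, the small and largely heterochromatic chromosome, departed most in relative terms. It had 13 peaks, 0.406% of the list (exact interval 0.216 to 0.693) against 1.01% of the assembled length of the arms. The gene gw on chromosome 4, singled out after its values were seen, was among the loci whose peak held the Cnc-Maf sequence (4:659888-660277, signal 165, rank 752). Smaller departures, also outside their intervals, were seen on 2L, with 19.5% of peaks (18.1 to 20.9) for 17.6% of length, and on 3L, with 19.1% (17.7 to 20.5) for 21.0%. The median distance between neighbouring summits was 15250 bp, and 234 of 3199 neighbouring pairs lay within 1 kb of each other.

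The strongest peaks lay at genes of varied function, and both replicates ranked them near the top. The highest signal, 1703, was at 2L:480902-481287, in an intron of ush and 1403 bp from the start site of cbt, a zinc finger transcription factor; cbt also had a promoter peak of signal 455 (rank 86). CG14100 followed (3L:19590436-19590797, signal 1624), 92 bp from its start site and with the Cnc-Maf sequence TGCATAGTCAT in its window. CG11050 came next with 1384 (2L:6612511-6612906, intron, 1027 bp from the start site). Ugalt, a UDP-galactose transporter, shared its peak (X:2703697-2704078, signal 1381) with eIF2Bbeta, a translation initiation factor. The plexus gene px (2R:22514113-22514487, signal 1307), the chromosomal protein gene Chro (3L:22878711-22879092, 1211), the kinase gene Lk6 (3R:11760868-11761223, 1198) and the arginine methyltransferase gene Art3 (3R:15229357-15229709, 1168) came after these. Ranks 9 to 15 were nearest to mRpL41, lncRNA:CR44619, ph-p, CG1888, PNPase, CHMP2B and CG32772, with signals from 1142 down to 909. All 15 stood within the first 17 ranks of both replicates.

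Genes of the cytosolic ribosome were the most often bound group. A summit within 1 kb of a start site was found at 66 of 92 ribosomal protein genes (71.7%, exact interval 61.4 to 80.6) against 19.0% of the other protein-coding genes, an odds ratio of 10.8 (6.75 to 17.7; Fisher's exact test, adjusted p = 2.38e-26 over 19 lists). RpS27 (3R:25247395-25247656, signal 542), RpL7 (2L:10200902-10201147, 463) and RpL34b (3R:9401172-9401522, 426) had the strongest peaks of the group. Over all protein-coding genes 2707 of 13968 (19.4%) had such a summit. The genes of basic leucine zipper factors, the family of maf-S itself, were bound at 10 of 19 (52.6%; odds ratio 4.63, 1.69 to 12.9; Fisher's exact test, adjusted p = 0.00385). Atf3 (X:1275323-1275690, signal 670, rank 33), the TORC1 effector REPTOR (3R:24572533-24572780, 369) and Irbp18 (3L:11098246-11098415, 296) led this group, which also included cnc, Jra, Xbp1, CrebA, CrebB, vri and maf-S. Among the 1602 peaks of highest signal the leucine zipper list no longer passed the threshold, with an odds ratio of 3.73.

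Cytochrome P450 and UDP-glycosyltransferase genes were bound less often than other genes. Of 85 cytochrome P450 genes 4 had a summit within 1 kb (4.71%; odds ratio 0.204, 0.0543 to 0.544; Fisher's exact test, adjusted p = 0.000844), namely Cyp6u1 (2R:6974876-6975265, signal 245), Cyp317a1, Cyp310a1 and Cyp6a2. None of 35 UDP-glycosyltransferase genes had one (adjusted p = 0.00335, Fisher's exact test), which allows a share of up to 8.57%, and this list no longer passed the threshold among the 1602 peaks of highest signal, where it again had 0 bound genes. Glutathione S-transferases had 2 of 35 (5.71%; odds ratio 0.252, Fisher's exact test, adjusted p = 0.106), GstE12 and GstE13, of which GstE13 (2R:9122016-9122367) had a signal of 821 and rank 20. Without replicate 3 there were 4 of 35 (odds ratio 0.527). The list of antioxidant and Cnc-Keap1 response genes did not differ detectably from other genes, with 12 of 55 bound (21.8% against 19.4%, odds ratio 1.16, 0.557 to 2.25, Fisher's exact test, adjusted p = 0.761). The count was 16 of 55 (odds ratio 1.68) without replicate 3 and 11 of 55 (1.07) without replicate 2, neither past the threshold. Members of the list bound by thresholded peaks included the divergent ferritin pair Fer1HCH and Fer2LCH, which share a peak (3R:30388489-30388666, signal 331). Others were the transporter gene MRP (2L:12721871-12722260, 271), Keap1, cnc, Sod1 and Trxr1. The thioredoxin reductase gene Trxr1 (X:8244236-8244625, signal 95.4, rank 2011) held the Cnc-Maf sequence TGCACCGTCAT. Genes often used as readouts of Cnc activity had no thresholded summit within 1 kb: the best peak of the pooled list ranked 3870 at GstD1, 4911 at Gclc, 5676 at Gclm and 17518 at ref(2)P. The same held for the Maf family gene tj (rank 12875) and for kay, the fly Fos gene (6162).

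Patterning genes were also rarely bound. Of 32 Hox and segmentation genes bcd had the only summit within 1 kb (3R:6759466-6759855, signal 114; 3.13%, odds ratio 0.134, 0.00328 to 0.804, adjusted p = 0.0361, Fisher's exact test); this list no longer passed the threshold without replicate 2 (odds ratio 0.285) or among the 1602 peaks of highest signal (0.260). Transfer RNA genes were bound at 26 of 290 against 16.8% of all other genes (8.97%; odds ratio 0.487, Fisher's exact test, adjusted p = 0.000844), with tRNA:Tyr-GTA-1-7 and tRNA:Tyr-GTA-1-8 at the strongest peak (3R:8669229-8669502, signal 386) and tRNA:Gln-TTG-2-1 at the next. The 26 genes lay at 16 peaks, and similar tRNA copies can share reads. Among the 1602 peaks of highest signal this list did not pass the threshold (odds ratio 0.558). None of 111 replication-dependent histone genes was bound (Fisher's exact test, adjusted p = 7.88e-10, an allowed share of up to 2.70%), but these are near-identical copies whose reads cannot be assigned uniquely, so this value is uncertain.

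The other lists did not pass the threshold of an adjusted p of 0.05. Proteasome subunits were bound at 11 of 32 (34.4%; odds ratio 2.18, 0.9496 to 4.74, Fisher's exact test, adjusted p = 0.0997), led by Rpn5 (signal 224), Rpn6 (170) and Rpn3 (164). This list passed the threshold without replicate 2 (odds ratio 2.58) and without replicate 3 (2.81). Autophagy genes were bound at 8 of 24 (Fisher's exact test, adjusted p = 0.218), among them Atg17, Atg18a and Atg2, and heat shock genes at 6 of 24 (adjusted p = 0.664), among them Hsp27, Hsp83 and Hsp26. Small nucleolar and small nuclear RNA genes had 53 of 301 (Fisher's exact test, adjusted p = 0.761), with scaRNA:MeU5-C46 and the pair snoRNA:U49:66Da and snoRNA:U49:66Db at the strongest peaks. The 53 genes lay at 34 peaks, of which 17, with 25 of the genes, were also peaks of ribosomal protein genes, the U49:66D pair sharing that of RpL14. For this list the distance decided the call: within 500 bp of a start site 19 were bound (odds ratio 0.412, past the threshold as lower), and within 5 kb 164 (2.39, past it as higher). Of the tissue markers, somatic muscle had 5 of 25 (Msp300 at signal 555, sls, TpnC47D, tin and Tm1; Fisher's exact test, adjusted p = 1), neurons and glia 3 of 25 (elav at 386, nrv2 and Nrg; 0.664), trachea and epidermis 3 of 19 (crb, shn and vvl; 1; without replicate 3, 5 of 19), midgut, fat body and haemocytes 3 of 23 (fkh, ush and Hnf4; 0.761) and germ line 3 of 13 (bgcn, orb and tud; 0.811). None of 10 ecdysteroid synthesis genes was bound (Fisher's exact test, adjusted p = 0.390), which allows a share of up to 30.0%.

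**Figure D2:**
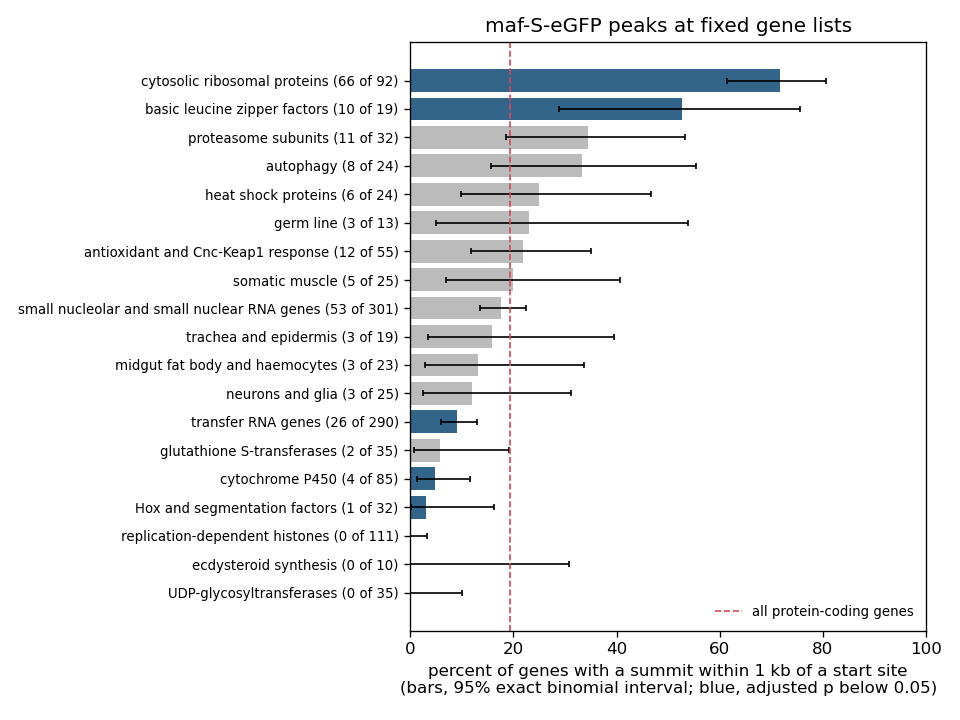
Percent of the genes of each list with a thresholded maf-S-eGFP summit within 1 kb of a start site, with exact binomial 95% intervals; blue bars passed an adjusted p of 0.05. Ribosomal protein genes stand at 71.7% and leucine zipper factors at 52.6%, against 19.4% of all protein-coding genes (dashed line; the RNA lists were compared with all other genes).

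The Cnc-Maf sequence RTGACNNNGCA was as rare under the peaks as beside them. It was present within 100 bp of 21 of 3205 summits (0.655%, exact interval 0.406 to 1.00) and in 45 of 6095 flanking windows at 1 kb (0.738%), an odds ratio of 0.887 (0.501 to 1.52; Fisher's exact test, two-sided, p = 0.698). In a single simulated split of flanks, 3000 windows against 3000, the same test called a site added to 15 windows (0.5%). This gives no detection rate. The 5 strongest peaks with the sequence were nearest to CG14100, lncRNA:CR44363 (3L:11405808-11406197, signal 244), CG10237 (2L:19439677-19439798, 242), Pgm1 (3L:16128612-16128792, 223) and CG10555 (X:8398698-8398804, 206). CG5439, named after its values were seen, alone held the longer sequence TGACTCAGCA (2L:13176911-13177300, signal 127, read on the other strand as TGCTGAGTCAC). The relaxed form TGACNNNGC was present at 5.74% of summits and 6.64% of flanks (odds ratio 0.856, 0.711 to 1.03). With the peaks in 5 equal groups by signal rank, RTGACNNNGCA was present at 1.09% of the strongest 641 peaks (7 peaks, exact interval 0.440 to 2.24) and at 0.312% to 0.780% of the other groups.

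Most of the peaks with the Cnc-Maf sequence were at promoters. They made up 18 of 1889 promoter peaks (0.953%) and 3 of 1316 other peaks (0.228%), the latter near CG10237, lncRNA:CR45348 and Atf3 (the last 2 named after their values were seen), an odds ratio of 4.21 (1.23 to 22.4; Fisher's exact test, p = 0.0131). This call was lost without replicate 2 (odds ratio 2.35) and with the relaxed sequence (1.33). Promoters with a peak did not hold the sequence detectably more often than promoters of genes without one (0.940% against 0.816%; odds ratio 1.15, 0.648 to 1.93). At peaks away from promoters its share was below that of their own flanks (0.228% against 0.767%, odds ratio 0.296, 0.0559 to 1.01, Fisher's exact test, unadjusted p = 0.0422). This rests on 3 peaks, and the interval includes 1, so the difference is uncertain. The relaxed sequence was also less frequent at these peaks than in their flanks (0.672, 0.493 to 0.908). Neither comparison was adjusted for the number of tests or used windows matched for GC content. Peaks with the sequence had a median signal of 127 and those without 109, a log2 difference of 0.22 (permutation test, two-sided, p = 0.237). The difference turned to -0.13 without replicate 2, and was 0.0145 within promoter peaks and 0.72 within other peaks, where 3 peaks held the sequence; none passed the threshold.

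Other sequences did stand out under the peaks, above all the DNA replication-related element (DRE) TATCGATA, a core promoter element bound by Dref. It was present at 184 summits (5.74%) against 0.492% of flanks, an odds ratio of 12.3 (8.31 to 18.8; Fisher's exact test, adjusted p = 8.62e-55 over a panel of 18 sequences). Motif 1, the promoter element GGTCACAC bound by M1BP, was present at 115 summits (3.59%) against 0.607% (odds ratio 6.09, 4.16 to 9.10; Fisher's exact test, adjusted p = 1.43e-24). Both were concentrated at promoters: the DRE lay under 178 of 1889 promoter peaks (9.42%) and 6 of 1316 others (0.456%), and motif 1 under 109 and 6. Summit windows were poorer in G and C than flanks (37.6% against 43.5%), and against GC-matched flanks the odds ratios were 7.46 for the DRE and 4.19 for motif 1. At ribosomal protein genes 17 of 66 peaks (25.8%) held the DRE against 7.70% of the other peaks within 1 kb of a start site (odds ratio 4.15, 2.19 to 7.54; Fisher's exact test, adjusted p = 0.000147 over 12 tests chosen after the data were seen).

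The remaining panel sequences gave smaller differences or none. The TATA box was more frequent at summits than in flanks (7.89% against 6.12%; odds ratio 1.31, Fisher's exact test, adjusted p = 0.00526), while the single Maf element TGCTGA (9.36% against 13.0%; 0.694, adjusted p = 1.22e-06) and the Mad sequence GCCGNCGC (1.40% against 2.87%; 0.482, adjusted p = 2.36e-05) were less frequent. The TATA box lost its call without replicate 3 (odds ratio 1.18), TGCTGA with windows of 50 bp (0.840) and Mad with windows of 250 bp (0.859). None of these 3 passed the threshold against the 2841 GC-matched flanks, where the odds ratios were 0.933, 0.849 and 1.02. AP-1 sites TGASTCA, bound by Jra and kay dimers, were present at 2.15% of summits and 1.99% of flanks (odds ratio 1.09, Fisher's exact test, adjusted p = 0.817), and the 3 reordered forms of the Cnc-Maf sequence did not pass (odds ratios 0.732, 0.932 and 0.622).

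**Figure D3:**
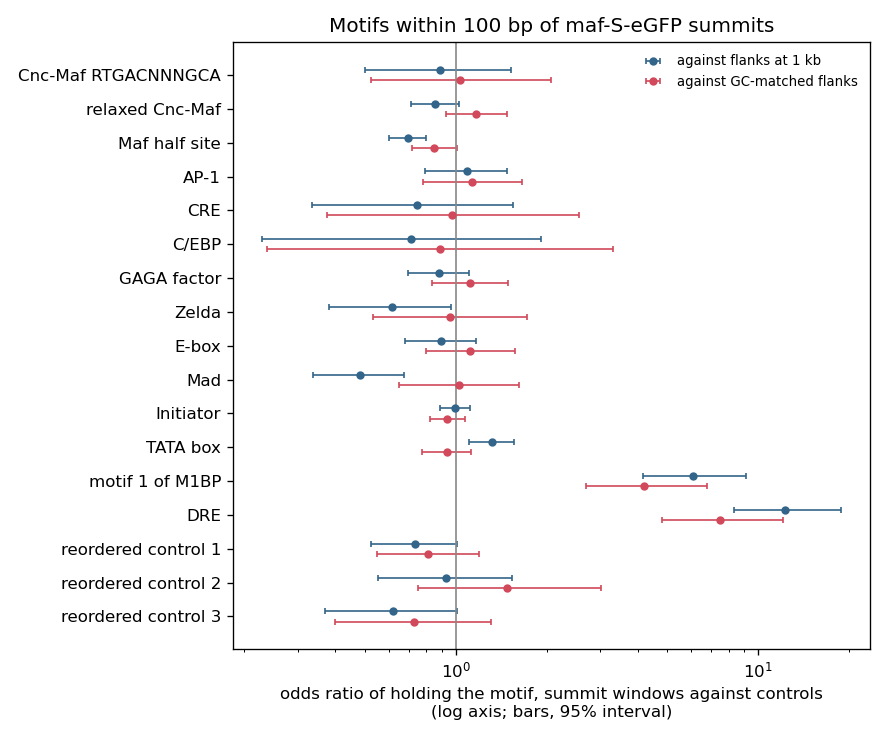
Odds ratio, on a log axis with 95% intervals, of holding each sequence within 100 bp of a thresholded maf-S-eGFP summit, against flanks at 1 kb (blue) and against GC-matched flanks (red). The DRE (12.3 and 7.46) and motif 1 (6.09 and 4.19) stand apart from the Cnc-Maf sequence (0.887 and 1.03); 2 sequences with at most 1 peak are not drawn.

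A search over all words without a chosen motif returned, among others, the DRE, motif 1, words with CACTG, words matching core promoter motif 7 and AT-rich words. Of 32896 words of 8 bp, 1603 were more frequent and 1967 less frequent in summit windows than in flanks (Fisher's exact test, Benjamini-Hochberg adjusted p below 0.05). Word counts below are out of 3205 summit windows and 6095 flanks. The leading words of 8 bp belonged to the DRE: ATCGATAG at 189 summits against 33 flanks, and ACTATCGA at 114 against 17. Words with CACTG on either strand followed, with CAACACTG at 148 against 42 and CACTGAGA at 108 against 19. GGTCACAC was also among the 25 leading words. So were CATCTCTA (90 against 19) and CAGCCCTG (83 against 19), which match CAKCNCTR, core promoter motif 7. AT-rich words such as TTTAAAAA (9.95% of summits against 4.51% of flanks) were among them too. Of the shorter words, 549 of 6 bp and 1252 of 7 bp were more frequent at summits and 853 and 2024 less frequent. The leading word of 6 bp was the AT-rich TTAAAA (46.4% of summits against 25.6% of flanks), followed by ACACTG (21.5% against 7.71%), and that of 7 bp was ATCGATA of the DRE (11.2% against 2.40%). Against GC-matched flanks 239 words were more frequent, and the 25 leading words of 8 bp of the first search were all among them.

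The replicates identified largely the same sites, most completely among the strong ones. Of the 3205 strongest peaks of replicate 2, 2445 (76.3%, exact interval 74.8 to 77.8) overlapped one of the 3205 strongest of replicate 3, and 75.6% in the other direction, against a mean of 1.70% and at most 2.28% for 100 random placements. Among the strongest 500 peaks of replicate 2 the share was 99.8%, and among its weakest 500 of the 3205 it was 43.4%. Thresholded peaks had a summit within 150 bp in replicate 2 in 3172 cases (98.97%) and in replicate 3 in 3192 (99.6%), and every thresholded peak was found in at least 1 replicate; vvl was among the 13 whose site was matched in replicate 2 only. Across the 3159 peaks matched in both, log2 signal gave Pearson's r = 0.79 and Spearman's rho = 0.68 (permutation test, two-sided, p = 1e-05 each, the smallest that 100000 permutations can give; peaks are not independent replicates, and the list was selected on the pooled signal). The signal was higher in replicate 3 by a mean of 0.42 on the log2 scale (SD 0.50 across peaks), but the lists were called separately and their scales are not comparable.

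**Figure D4:**
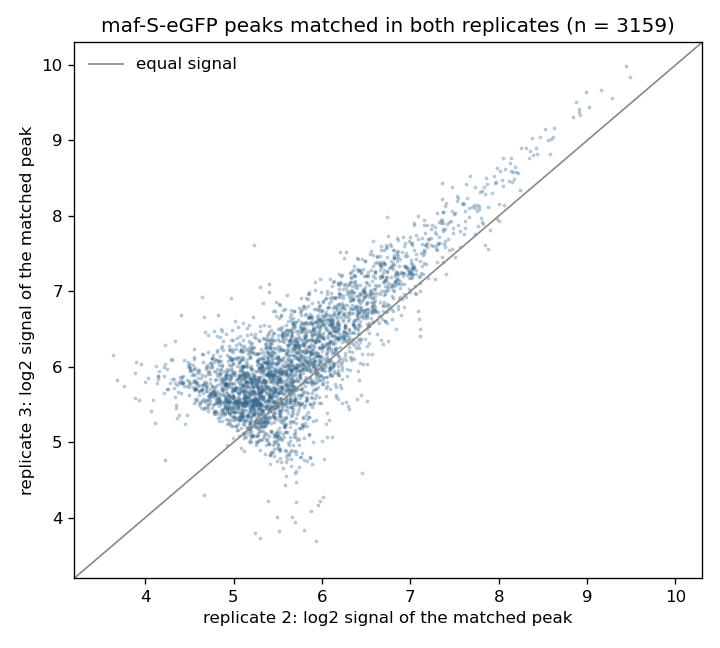
Log2 signal of 3159 thresholded maf-S-eGFP peaks in replicate 2 (x axis) and replicate 3 (y axis), a point for each peak matched within 150 bp; the line marks equal signal. Points rise together (Pearson's r = 0.79) and lie on average 0.42 above the line.

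The lists on the older dm3 assembly were compared with dm6 without coordinates. The dm3 thresholded list held 3508 peaks with signal values from 67.96 to 1702 and a median of 103, and both lists had a median width of 390 bp. Chromosome 4 held 0.399% of the dm3 peaks. Between the dm3 lists of the replicates, the overlap of the strongest peaks was 76.4% and Spearman's rho 0.68.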

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

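GC-matched windows and smaller random control sets for the motif panel and the word search, single-replicate lists for the panel, the word search and peak strength, and the omission of Y genes were chosen after seeing the data; the other alternatives were planned. Of 254 alternative values over 38 results, 195 kept their direction and their side of the threshold, or stayed within their interval or 1.5 times of the count. The promoter share (49.8% to 68.5%), the replicate overlap (69.0% to 79.6%), the rank correlation (0.676 to 0.729) and the odds ratios of the DRE (7.46 to 15.7), motif 1 (4.19 to 6.63) and ribosomal protein genes (8.28 to 12.6) did so under each alternative run. The N strongest peaks of the pooled list are the thresholded list itself, so that alternative tests nothing and is not counted. The stricter threshold keeps the 1602 peaks of highest signal by construction, and called 3 gene lists in place of 7, losing UDP-glycosyltransferases, leucine zipper factors, Hox genes and transfer RNA genes; a start site distance of 5 kb called 12, adding glutathione S-transferases, proteasome subunits, autophagy, ecdysteroid synthesis and small nucleolar and nuclear RNA genes. The odds ratio of the small nucleolar and nuclear RNA genes was 0.412 at 500 bp, 2.39 at 5 kb, 0.777 over gene bodies and 0.962 to 0.992 without replicate 2 or 3. Never past the threshold, somatic muscle turned to 0.701 among the 1602 strongest peaks and 0.778 to 0.816 without replicate 2 or 3, and trachea and epidermis to 1.04 at 5 kb, 2.10 over gene bodies and 0.504 to 1.46 without replicate 2 or 3. The Cnc-Maf odds ratio, never past the threshold, moved above 1 with windows of 50 bp (1.13), GC-matched windows (1.03) and the strict sequence (1.90), and ran from 0.793 to 1.10 without replicate 2 or 3. GC-matched windows reduced the panel calls from 5 to 2 and the 8 bp words from 1603 to 239, and turned the TATA box (0.933) and Mad (1.02) across 1. The matched set has 2841 windows in place of 6095; as many flanks drawn at random gave 961 words and 5 panel calls, losing the TATA box (1.26) and adding Zelda, so the smaller set accounts for part of the drop in words and not for the drop in the number of panel calls. The difference in Cnc-Maf sequences between promoter and other peaks lost its call among the 1602 strongest peaks (odds ratio 2.69), with the relaxed sequence (1.33) and at 250 bp (2.53), and was 2.35 to 3.01 without replicate 2 or 3. The log2 strength difference, never past the threshold, was -5.95e-05 with the relaxed sequence, -0.015 with windows of 250 bp, and -0.13 to 0.19 without replicate 2 or 3. Thresholded peaks were found in replicate 2 in 97.1% at 100 bp, 99.9% at 250 bp, 99.9% by overlap and 83.7% among the N strongest replicate peaks; in replicate 3 these were 98.4%, 99.97%, 99.9% and 88.4%. The locus of maf-S had 14 peaks in each replicate before thresholding in place of 2. Proteasome subunits passed the threshold in 4 of 8 alternatives, and also against genes matched for length; the Hox list lost it in 4 of 8. Except where the construction shows it, the cause was not tested. Read depth, not given in the sources used here, limits what the weaker peaks can show.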

Other observations

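The tests of gene groups by symbol prefix, of promoter motifs 5 and 7 and CTCF, of the rank bins and of the 500 and 641 strongest peaks were chosen after the results were seen. Genes of these groups can share a peak with a gene outside the group, as Nup154 does with RpL9, eIF1 with RpL28 and mRpS10 with Art3. Nucleoporin genes had a summit within 1 kb of a start site at 9 of 21 (42.9%; odds ratio 3.13, 1.16 to 8.09; Fisher's exact test, adjusted p = 0.0253 over 13 groups), led by Nup37, which shares its peak with RpS27, and Nup98-96. Proton ATPase subunits were bound at 13 of 33 (39.4%; 2.71, 1.24 to 5.74; Fisher's exact test, adjusted p = 0.0182), with Vha14-1 and Vha100-2 first, and translation initiation factors at 15 of 44 (34.1%; 2.16, 1.07 to 4.17; adjusted p = 0.0377), with eIF2Bbeta, eIF6 and eIF3c first. Mitochondrial ribosomal protein genes were bound at 22 of 73 (30.1%; 1.80, 1.04 to 3.03; Fisher's exact test, adjusted p = 0.0412), and mRpS10, mRpL41 and mRpS23 lay at peaks ranked 8, 9 and 17. Mediator subunits (7 of 25, Fisher's exact test, adjusted p = 0.349), RNA polymerase subunits (9 of 31, 0.227), genes with the Rab prefix (8 of 31, 0.364) and NADH dehydrogenase subunits (5 of 40, namely ND-MWFE, ND-ASHI, ND-51, ND-24 and ND-SGDH; 0.349) did not pass the threshold.

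Genes of sensory receptors and of the cuticle were almost free of peaks. None of 59 odorant receptor genes was bound (Fisher's exact test, adjusted p = 4.28e-05), which allows a share of up to 5.08%, and none of 70 cuticular protein genes of the Cpr family (adjusted p = 5.21e-06, up to 4.29%). Gustatory receptors had 1 of 60 (Gr63a, Fisher's exact test, adjusted p = 0.000179) and ionotropic receptors 1 of 60 (Ir60e, adjusted p = 0.000179). The Jonah serine proteases had 0 of 16 (Fisher's exact test, adjusted p = 0.0785, up to 18.8%).

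Promoter elements were rarer at the weak end of the pooled list than at its strong end, and the Cnc-Maf sequence was not. From the first 3000 peaks to ranks 27001 to 30000, the promoter share went from 59.4% to 20.6%, the DRE from 5.53% (4.74 to 6.41) to 0.667% (0.408 to 1.03) and motif 1 from 3.50% (2.87 to 4.22) to 0.733% (0.460 to 1.11). The Cnc-Maf sequence stood at 0.600% (0.356 to 0.947) and 0.800% (0.513 to 1.19) in these bins, and between 0.600% and 1.23% in all 10. Inside the thresholded list the DRE and motif 1 did not fall with signal. From the strongest 641 peaks to the weakest 641, the DRE went from 4.06% (2.67 to 5.89) to 6.40% (4.63 to 8.58). Motif 1 went from 2.50% (1.43 to 4.02) to 4.68% (3.18 to 6.61), while the promoter share went from 65.8% to 55.4%. No biological explanation was tested for these differences.

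The Cnc-Maf sequence was not enriched under maf-S-eGFP peaks (odds ratio 0.887). Windows of 250 bp either side, which allow for summits placed off the site, showed no excess, with an odds ratio of 0.986 (0.704 to 1.37). A small excess within that interval is not excluded. For the relaxed sequence, dilution by weak peaks was not seen, with 0.982 (0.595 to 1.59) among the 500 strongest peaks. For RTGACNNNGCA itself dilution stays open: 7 of the 641 strongest peaks and 5 of their 1200 flanks held it, an odds ratio of 2.64 with an interval of 0.717 to 10.6. Open as well are the GC content of the summits, with an odds ratio of 1.03 (0.524 to 2.06) against GC-matched flanks, and, untested here, signal that any GFP-tagged protein may give at open promoters, which needs a control precipitation.

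The DRE and motif 1 were enriched under the peaks, and 2 technical readings did not account for all of the DRE excess. Against GC-matched flanks the DRE odds ratio was 7.46 (4.80 to 12.1), below the 12.3 against all flanks. Promoters with a peak held it at 9.85%, against 4.07% of promoters of genes without one (odds ratio 2.58, 2.15 to 3.08). These were read at the same distances from the start. For motif 1 that promoter comparison gave 2.01 (1.61 to 2.50). Flanks at 1 kb held the DRE at 0.492%, so promoters in general and GC content can each account for part of the excess. Peaks away from promoters showed no such DRE excess over their own flanks (0.805, 0.253 to 2.24, from 6 peaks with the DRE). That interval lies below the 12.3 (8.31 to 18.8) of all peaks. Whether a smaller excess exists there stays open. A hypothesis that the peaks gather at promoters built from the elements of broadly active genes predicted an excess of core promoter motif 6, KTYRGTATWTTT. That excess was not seen over promoters without a peak (odds ratio 0.789, 0.439 to 1.33). The test rests on a single element, held by 16 of 1808 promoters with a peak, so the hypothesis stays open. Core promoter motifs 7, CAKCNCTR (3.26, 2.89 to 3.68), and 5, AWCAGCTGWT (1.69, 1.22 to 2.29), were in excess in that comparison. So was the CTCF sequence AGRKGGCGC (4.15, 2.75 to 6.18). The excesses of motifs 7 and 5 lie in the direction predicted for motif 6. Both motifs were chosen after the results were seen, so they do not decide the hypothesis. Over all peaks against GC-matched flanks, the CTCF sequence had an odds ratio of 11.6 (5.67 to 27.7), against 7.46 for the DRE, with overlapping intervals. Motif 5 gave 6.10 (3.01 to 14.0), motif 7 4.49 (3.66 to 5.54) and motif 6 1.26 (0.565 to 2.89). The word search of the same windows also returned AGATGGCG, part of the CTCF sequence, and CATCTCTA, a match to motif 7. The excesses of CTCF and motif 7 are therefore not independent of that search, unlike the DRE, which was fixed beforehand. Binding of maf-S through other proteins and the general openness of these promoters remain untested candidates.

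The peak over the maf-S gene could reflect extra copies of the locus carried by the transgene, which would raise the whole region. The pooled list had 14 peaks within 20 kb of maf-S, more than 50.2% of protein-coding genes had and close to their median of 13. This count cannot decide the question. Extra copies would raise coverage and need not add called peaks, and no control coverage was analysed. A local effect of the tagged gene at the summit itself was not tested, and the summit also lies 97 bp from the start site of CG11110.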
